A study of Mus musculus with 24 samples.

How the data were processed

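Liver RNA of 24 LDLR knockout mice was measured by sequencing, with 6 livers in each of 4 groups: ad libitum fed, ad libitum fasted, TRF fed and TRF fasted. Per the labels' protocols, total RNA was extracted with TRIzol from powdered frozen liver and libraries were made with a strand-specific kit that selects polyadenylated RNA. The deposited values are whole-number read counts per gene, made by the authors with STAR 2.5.3a on the mouse build mm10, per the submitters' processing notes, which also name FastQC 0.11.5 and edgeR 3.26.7. The gene annotation and the strand setting of the counting are not given in the sources used here, so reads of genes that overlap on opposite strands cannot be assigned with certainty. The count table held 52390 gene IDs, and every per-sample column belonged to 1 of the 24 libraries. Gene symbols came from the table; 157 IDs without a symbol held 0.0163% of the counts and stayed in the library totals and tests under their ID, and 62 IDs whose symbol belonged to another ID with more counts were named by ID. Coordinates are 1-based positions in GRCm38 from GENCODE release 21 of the mouse annotation (M21), found by Ensembl ID for 52081 of the 52390 IDs and 14951 of the 14967 tested, because the coordinates in the count table did not match that release for most genes.

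Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by the edgeR function filterByExpr with the 4 groups, which left 14967 genes holding 99.94% of the counts. Library sizes were scaled by TMM factors, which ranged from 0.925 to 1.26. A quasi-likelihood model with robust estimation and 1 mean per group was fitted to all 24 libraries, so that the groups shared 1 estimate of the spread; it had 20 residual degrees of freedom, a median of 5.8 prior degrees of freedom and a common biological coefficient of variation of 0.21. The contrasts were TRF minus ad libitum in each state and in the mean of both states, fasted minus fed under each regimen, and the difference of the last 2 (interaction). P-values of 2-sided tests were adjusted by Benjamini-Hochberg over all genes of a contrast, with a threshold of 0.05. For 46 gene lists of pathways and cell types, camera was run with the preset inter-gene correlation of 0.01 and again with an estimated one, and fry was run beside it, each adjusted over the 46 lists of a contrast. Groups, contrasts, lists, the rule for naming genes and all alternatives not said to be later were fixed before the data were examined. Named genes were, for each contrast but the mean of both states, the 8 with the largest change in each direction (5 for the interaction) among called genes with a mean of at least 5 CPM in the higher group and a symbol of a known gene; for each called list the 2 called members with the smallest p in its direction; and a fixed panel read in every contrast. Members named to say what a list's moved genes are, and other genes said to be so, were chosen after their values were seen. Mean ± SD values are CPM from TMM-scaled library sizes over 6 livers.

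The alternatives were RLE size factors, library sizes alone, no filter on low counts, a filter of at least 5 CPM in 1 group, DESeq2, limma-voom with sample quality weights, estimation without robust weights, only the groups compared, the replicate number as a block, the share of counts in the 100 most abundant genes as a covariate, and each library left out in turn. Fits without the 3 livers with pancreatic transcripts, and list tests and correlations without TRF fasted liver 1, were added after the data were seen. Chance was examined with 100 splits of the libraries per contrast. No pair of libraries in a group was a duplicate: the lowest chi-square per degree of freedom among 60 pairs was 13.4. The code was tested on simulated data drawn for TRF fed against ad libitum fed livers with 200 of 14967 genes changed: it recovered 51% of genes changed 1.5-fold, 78.5% of those changed 2-fold and 96% of those changed 4-fold, and called 3, 10 and 8 unchanged genes. Changes under 1.5-fold are therefore often missed with 6 livers at 23.6 to 38.7 M counts. Each liver is treated as a separate animal, which the labels imply by giving each its own sample; where livers were processed together is not given in the sources used here.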

Results

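The data set held liver transcriptomes of 24 mice that lack the low density lipoprotein receptor (LDLR), a model of atherosclerosis. The mice were fed ad libitum or by time-restricted feeding (TRF), in which food is offered during part of the day only. Livers of both regimens were taken in the fed or in the fasted state, with 6 livers in each of the 4 groups. A sample sheet with the counts gave the time value 16 to all fed and 10 to all fasted livers, with no unit. Fed and fasted livers thus also differed in this value, while the regimens shared it within a state. Whether food was removed from the ad libitum mice of the fasted state is not given in the sources used here. Libraries held 23.6 to 38.7 M (mega) counts, with means of 33.7 ± 2.94 M in ad libitum fed, 31 ± 3.92 M in ad libitum fasted, 29.9 ± 3.27 M in TRF fed and 31.6 ± 4.44 M in TRF fasted livers (n = 6 each). Of 28858 genes with a count, 14967 passed the filter on low counts and were tested. Levels below are mean ± SD values in CPM, counts per 1 M counts of the scaled library, of 6 livers per group, and values marked log2 are log2 fold changes ± standard error. A gene rose or fell where its adjusted p was under 0.05.

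Transcripts of Ldlr (ENSMUSG00000032193, chromosome 9, 21723483 to 21749919 in GRCm38), the receptor gene targeted in this strain, were counted in every liver at 171.7 to 399.2 CPM. Group means were 272 ± 73.5 and 309.7 ± 46.2 CPM in ad libitum fed and fasted livers and 258 ± 49.2 and 258 ± 53.9 CPM in TRF fed and fasted livers, and no comparison called the gene. A gene-level count includes reads from any part of a disrupted gene and no wild-type library was analysed here, so these values do not check the genotype. The first principal component held 20.9% of the variance, the second 16.4% and the third 14.6%. TRF fasted liver 1 stood apart from the other 23 livers, at -79.3 on the second component. Elovl3, an elongase with male-biased expression, was at 0.242 CPM in it against 51.2 to 57.9 CPM in the other 5 livers of its group. Cyp2a4, a cytochrome P450 with female-biased expression, was at 193 CPM against at most 0.235 CPM. Transcripts of pancreatic acinar cells, which make digestive enzymes, reached 1110 CPM in ad libitum fed liver 3, 276 CPM in TRF fed liver 6 and 75.4 CPM in TRF fed liver 4. They reached at most 2.77 CPM in the other livers.

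**Figure D1:**
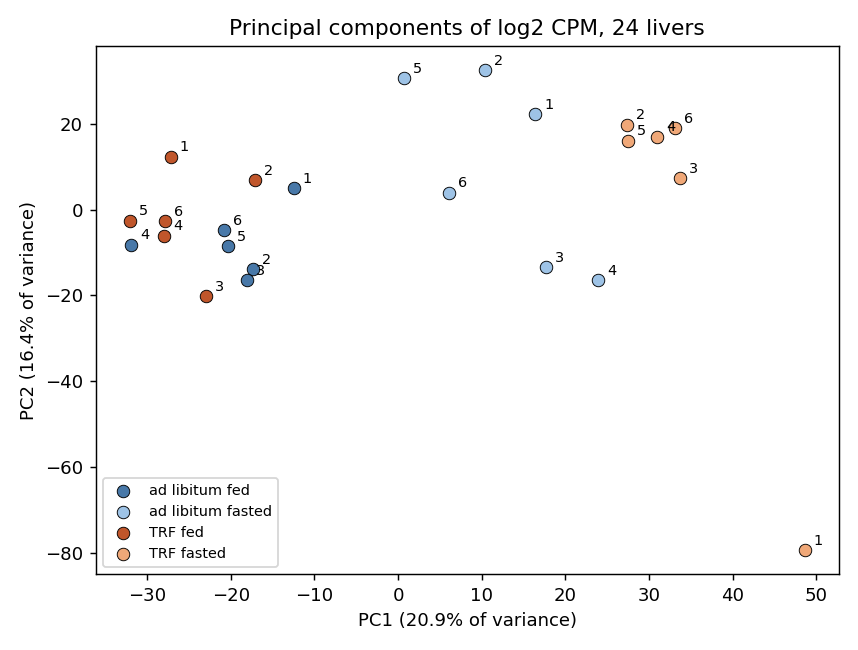
Principal components of log2 CPM values of the 24 livers. Each point is 1 liver, coloured by group, with its replicate number beside it. The horizontal axis is component 1 (20.9% of the variance) and the vertical axis component 2 (16.4%). TRF fasted liver 1 lies apart from the others at -79.3 on component 2.

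The first comparison asked how TRF altered the liver in the fed state. Under TRF 6 of 12 E-box and D-box clock genes, 8 of 13 heat shock genes and 6 of 17 acute phase genes were higher, and 8 of 18 genes for the metabolism of drugs were lower. No list was called with an estimated correlation. Per2, a repressor in the core clock (ENSMUSG00000055866, chromosome 1, 91415982 to 91459324 in GRCm38), rose from 58.6 ± 11.7 to 113 ± 19.6 CPM (log2 0.94 ± 0.16, edgeR adjusted p = 0.00042, n = 6 per group). Nr1d1, a nuclear receptor that represses Arntl, rose from 2.6 ± 1.39 to 7.51 ± 2.6 CPM (log2 1.54 ± 0.30, edgeR adjusted p = 0.0024). Bag3, a co-chaperone of HSP70, rose from 41.7 ± 6.48 to 74.7 ± 19.5 CPM (log2 0.84 ± 0.19, edgeR adjusted p = 0.0076). Cyp2c29, a cytochrome P450 (ENSMUSG00000003053, chromosome 19, 39269405 to 39330713), fell from 1187 ± 259 to 518 ± 190.3 CPM (log2 -1.20 ± 0.20, edgeR adjusted p = 0.00042).

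Of 12 E-box and D-box clock genes, 6 rose and 6 did not pass (camera adjusted p = 3.5e-06, adjusted p = 0.34 with an estimated correlation). With p adjusted over the list alone, 6 rose. Of 13 heat shock genes, 8 rose and 5 did not pass (camera adjusted p = 2.3e-07, adjusted p = 0.39 with an estimated correlation). Counting members adjusted over the list alone, 12 rose. Of 18 xenobiotic genes, 8 fell and 10 did not pass (camera adjusted p = 4e-06, adjusted p = 0.34 with an estimated correlation). With members adjusted over the list alone, 1 rose and 12 fell. Of 17 genes of the acute phase, the secretory response to inflammation, 6 rose and 11 did not pass (camera adjusted p = 0.0005, adjusted p = 0.87 with an estimated correlation). When adjusted over the list alone, 9 rose. Limma-voom called 2 of them. Of 15 NRF2 targets, which defend against oxidants, 3 fell and 12 did not pass (camera adjusted p = 0.0044, adjusted p = 0.87 with an estimated correlation). If adjusted over the list alone, 3 fell. Of 8 markers of B cells and plasma cells, 3 fell and 5 did not pass (camera adjusted p = 0.0012, adjusted p = 0.74 with an estimated correlation). By p-values adjusted over the list alone, 5 fell. These were scarce, as for Cd79b, part of the B cell receptor, at 1.19 ± 0.194 and 0.497 ± 0.17 CPM. Also called were extracellular matrix (2 rose of 19, 3 rose adjusted over the list alone), cell cycle (1 rose of 22, 1 rose adjusted over the list alone) and mitochondrially encoded genes (1 fell of 19, 1 fell adjusted over the list alone), with camera adjusted p from 0.00014 to 0.0025, and adjusted p from 0.85 to 0.87 with an estimated correlation. The matrix call ended without TRF fed liver 3 (camera adjusted p up to 0.055). The neutrophil list was called upwards (camera adjusted p = 0.014, adjusted p = 0.87 with an estimated correlation) with 0 of 8 members past the edgeR threshold and 4 adjusted over the list alone. In the whole list, 6 were higher at an unadjusted p under 0.05, with 2 called by DESeq2 and 0 by limma-voom. The neutrophil call ended without ad libitum fed liver 2 or TRF fed liver 3 (camera adjusted p up to 0.074). TRF fed livers 3, 5 and 6 stood apart from livers 1, 2 and 4 on the third principal component (-39.2 to -37 against -14.8 to 9.86), a split seen only after the tests. Their heat shock means were 7.4 to 7.56 log2 CPM, against 6.83 to 7.11 in the other 3 and 6.16 to 6.85 in ad libitum fed livers. Matrix means were 3.76 to 4.47, against 3.13 to 3.58 and 3.09 to 3.53, and cell cycle means 1.62 to 2.1, against 1.08 to 1.41 and 0.78 to 1.31. Acute phase means were 9.91 to 10.54, against 8.26 to 9.69 and 8.54 to 9.07, and xenobiotic means 6.03 to 6.13, against 6.22 to 7.12 and 7.18 to 7.63. Hspb1, a small heat shock protein, was at 75.1 to 84.2 CPM in these 3 livers, 22 to 41.2 CPM in the other 3 and 17.6 to 46.5 CPM in ad libitum fed livers.

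Among the largest increases in fed livers were the metal-binding metallothionein Mt2 (from 9.24 ± 2.02 to 166 ± 208 CPM, log2 4.17 ± 0.87, edgeR adjusted p = 0.0045) and the chemokine Cxcl1 (from 8.61 ± 2.57 to 65.9 ± 68.9 CPM, log2 2.93 ± 0.64, edgeR adjusted p = 0.0063). Without TRF fed liver 5, at 573.3 CPM against 5.5 to 168.8 CPM in the other 5, Mt2 went to log2 3.2 (edgeR adjusted p = 0.015). The rise of Cxcl1 lay in TRF fed livers 3, 5 and 6 (70.3, 131.2 and 165.2 CPM), while livers 1, 2 and 4 were at 9.8, 5.2 and 13.6 CPM and ad libitum fed livers at 6.3 to 13.4 CPM. Igfbp1, a binding protein of growth factors, was also at 90.1 to 175.3 CPM in livers 3, 5 and 6, against 4.5 to 32.5 CPM in the other 3. The largest decreases included Cfd, the complement protease adipsin (from 23.9 ± 15.6 to 1.5 ± 1.62 CPM, log2 -4.02 ± 0.95, edgeR adjusted p = 0.01), which went to log2 -4.68 without TRF fed liver 2. Reads of Mt1 and Mt2, near copies, can be shared, and 73.5% of the exon bases of Mt2 lie in a gene on the other strand, so its value is uncertain. Increases of 2 genes rested on 1 liver each. Egr1, an immediate early gene, went from log2 2.81 to 1.16 (edgeR adjusted p = 0.14) without TRF fed liver 6. Slc4a1, an erythrocyte anion exchanger, went from log2 3.09 to 1.06 (edgeR adjusted p = 0.36) without TRF fed liver 3. Of the genes read in every comparison, Dbp, a clock output factor, rose (log2 0.95 ± 0.21, edgeR adjusted p = 0.0048). Arntl, the clock activator BMAL1, fell (log2 -0.67 ± 0.18, edgeR adjusted p = 0.019), a call that ended without ad libitum fed liver 5 or TRF fed liver 6 (edgeR adjusted p up to 0.051). Pck1, of gluconeogenesis, rose (log2 1.10 ± 0.36, edgeR adjusted p = 0.049), a call that ended in 10 of 12 fits with 1 liver left out (edgeR adjusted p up to 0.11), and its value was log2 1.64 without ad libitum fed liver 1. Those that did not pass had log2 values of -0.07 for Ldlr, 0.45 for Cyp7a1, 0.63 for Hmgcr, 0.72 for Pcsk9, 0.29 for Srebf1, 0.44 for Fasn, -0.48 for Scd1, -0.01 for Gck, -0.05 for Cpt1a, -0.20 for Hmgcs2, -0.37 for Fgf21 and 1.62 for Igfbp1 (edgeR adjusted p from 0.07 to 0.98). Of these, Igfbp1 was log2 2.22 without ad libitum fed liver 1 (edgeR adjusted p = 0.047), Hmgcr passed without TRF fed livers 2 or 4 and Igfbp1 passed without TRF fed liver 1.

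For TRF minus ad libitum, fed, 1631 of 14967 genes passed, 859 higher and 772 lower, and 669 changed by at least 1.5-fold. Camera called 10 of 46 lists, 6 higher and 4 lower and fry called 6. The count of genes was 1077 with no filter on low counts, 1011 without ad libitum fed liver 5, and 1082, 926 and 942 without TRF fed livers 3, 5 and 6. It was 887 without the 3 livers with pancreatic transcripts, an alternative chosen after the data were seen.

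The second comparison asked how TRF altered the liver in the fasted state. Under TRF 10 of 23 cholesterol synthesis genes, 8 of 21 fatty acid synthesis genes and 10 of 13 heat shock genes were lower. No list was called with an estimated correlation. Thrsp, a regulator of lipid synthesis (ENSMUSG00000035686, chromosome 7, 97412938 to 97417730 in GRCm38), fell from 922 ± 372 to 180.1 ± 123 CPM (log2 -2.36 ± 0.39, edgeR adjusted p = 0.001, n = 6 per group). Fasn, fatty acid synthase (ENSMUSG00000025153, chromosome 11, 120805846 to 120824547), fell from 623 ± 263 to 169 ± 83.2 CPM (log2 -1.89 ± 0.42, edgeR adjusted p = 0.0084). Gck, the glucokinase that traps glucose in hepatocytes (ENSMUSG00000041798, chromosome 11, 5900820 to 5950081), fell from 172 ± 55.4 to 71.1 ± 17.4 CPM (log2 -1.27 ± 0.20, edgeR adjusted p = 0.00051). Trib3, a pseudokinase induced by cell stress (ENSMUSG00000032715, chromosome 2, 152337422 to 152344032), rose from 2.81 ± 1.01 to 14 ± 8.68 CPM (log2 2.32 ± 0.29, edgeR adjusted p = 3.9e-05).

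Of 23 cholesterol synthesis genes, 10 fell and 13 did not pass (camera adjusted p = 1.1e-13, adjusted p = 0.18 with an estimated correlation). Where p was adjusted over the list alone, 13 fell. Hmgcr, the rate-limiting enzyme, fell from 91.1 ± 30.1 to 45.7 ± 7.73 CPM (log2 -0.99 ± 0.22, edgeR adjusted p = 0.0092). In a split seen only after the test, ad libitum fasted livers 1, 2 and 5 (22.2 to 32.5 on the second component) held 95 to 126.6 CPM of Hmgcr and 269 to 342.4 CPM of Insig1, against 48.2 to 79.7 and 101.2 to 195.2 CPM in livers 3, 4 and 6 (-16.4 to 3.92). TRF fasted livers held 37.4 to 56.9 and 60.4 to 99.8 CPM. Of 21 fatty acid synthesis genes, 8 fell and 13 did not pass (camera adjusted p = 4.8e-10, adjusted p = 0.31 with an estimated correlation). Among members adjusted over the list alone, 11 fell. Of 15 glycolysis genes, 5 fell and 10 did not pass (camera adjusted p = 0.00027, adjusted p = 0.48 with an estimated correlation). Using p adjusted over the list alone, 6 fell. Of 13 heat shock genes, 10 fell and 3 did not pass (camera adjusted p = 6.3e-13, adjusted p = 0.12 with an estimated correlation). Once adjusted over the list alone, 11 fell. Hspa8, the constitutive HSP70 (ENSMUSG00000015656, chromosome 9, 40800984 to 40810087 in GRCm38), fell from 1238 ± 249.6 to 773 ± 116 CPM (log2 -0.68 ± 0.15, edgeR adjusted p = 0.006). Of 18 chaperones of the endoplasmic reticulum (ER), 2 fell and 16 did not pass (camera adjusted p = 3.2e-07, or 0.62 with an estimated correlation). Of 18 xenobiotic genes, 6 fell and 12 did not pass (camera adjusted p = 4.4e-10, or 0.11 with an estimated correlation). Of 5 clock genes of the opposite phase, 3 fell and 2 did not pass (camera adjusted p = 0.00087, or 0.061 with an estimated correlation). Adjusted over each list alone, 11 ER chaperones, 10 xenobiotic and 3 clock genes fell. Arntl fell from 2.46 ± 1.28 to 0.945 ± 0.195 CPM (log2 -1.40 ± 0.22, edgeR adjusted p = 0.00051). Of 12 E-box and D-box clock genes, 4 rose, 1 fell and 7 did not pass (camera adjusted p = 0.019, adjusted p = 0.69 with an estimated correlation). When adjusted over the list alone, 4 rose and 1 fell. The gene that fell was Rorc, an activator of Arntl, chosen after its value was seen, and Dbp rose (log2 1 ± 0.19, edgeR adjusted p = 0.0025). The E-box call ended without ad libitum fasted liver 4 or TRF fasted liver 2 (camera adjusted p up to 0.059), and that of Nr1d1 (log2 1 ± 0.27, edgeR adjusted p = 0.026) ended without ad libitum fasted liver 6 or TRF fasted liver 3 (edgeR adjusted p up to 0.077).

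Of 17 genes of the integrated stress response, 4 rose and 13 did not pass (camera adjusted p = 0.01, adjusted p = 0.77 with an estimated correlation). If adjusted over the list alone, 5 rose. The call of this list ended without TRF fasted liver 1 (camera adjusted p up to 0.21). Of 34 genes of fatty acid oxidation and ketogenesis, 3 rose and 31 did not pass (camera adjusted p = 0.019, adjusted p = 0.88 with an estimated correlation). By p-values adjusted over the list alone, 4 rose. The oxidation call ended in 3 of 12 fits with 1 liver left out (camera adjusted p up to 0.31). Of 14 bile acid synthesis genes, 2 fell and 12 did not pass (camera adjusted p = 0.019, adjusted p = 0.77 with an estimated correlation). Where p was adjusted over the list alone, 1 rose and 4 fell. The bile acid call ended without TRF fasted liver 1 (camera adjusted p up to 0.63). The extracellular matrix list was called upwards (camera adjusted p = 0.00025, or 0.77 with an estimated correlation) with 0 of 19 members past the edgeR threshold and 10 adjusted over the list alone. In all, 10 were higher at an unadjusted p under 0.05, with 7 called by DESeq2 and 3 by limma-voom. Its mean was 4.95 log2 CPM in TRF fasted liver 1 (camera adjusted p = 0.032 without it). The other 5 (3.18 to 3.91) lay in the ad libitum fasted range (2.92 to 3.93). The cholangiocyte list, of bile duct cells, was called upwards (camera adjusted p = 0.011, or 0.62 with an estimated correlation) with 0 of 7 members past the edgeR threshold and 5 adjusted over the list alone. In this list, 5 were higher at an unadjusted p under 0.05, with 2 called by DESeq2 and 0 by limma-voom. The stellate cell list was called upwards (camera adjusted p = 0.043, adjusted p = 0.62 with an estimated correlation) with 0 of 10 members past the edgeR threshold and 1 adjusted over the list alone. In the whole list, 4 were higher at an unadjusted p under 0.05, with 1 called by DESeq2 and 1 by limma-voom. The Kupffer cell list, of resident macrophages, was called downwards (camera adjusted p = 0.043, adjusted p = 0.77 with an estimated correlation) with 0 of 12 members past the edgeR threshold and 3 adjusted over the list alone. Of all its members, 3 were lower at an unadjusted p under 0.05, with 1 called by DESeq2 and 2 by limma-voom. Other called lists were neutrophils (1 rose of 8, 3 rose adjusted over the list alone), oxidative phosphorylation (1 fell of 24, none passed adjusted over the list alone), interferon response (1 fell of 19, 1 fell adjusted over the list alone), NRF2 targets (1 fell of 15, 1 fell adjusted over the list alone) and mitochondrially encoded genes (1 fell of 19, 1 fell adjusted over the list alone), with camera adjusted p from 0.0017 to 0.026, and adjusted p = 0.77 with an estimated correlation. Of the oxidative phosphorylation genes, 6 were lower at an unadjusted p under 0.05, 2 by DESeq2 and 2 by limma-voom. The cholangiocyte and mitochondrial calls ended without TRF fasted liver 1 (camera adjusted p up to 0.13 and 0.12). The interferon call ended without ad libitum fasted liver 4 (camera adjusted p up to 0.063) and the NRF2 call ended in 3 of 12 fits with 1 liver left out (camera adjusted p up to 0.097). The stellate and Kupffer cell calls each ended in 5 of 12 fits with 1 liver left out (camera adjusted p up to 0.12 and 0.33). The neutrophil call ended in 6 of 12 fits with 1 liver left out (camera adjusted p up to 0.13), and limma-voom called 0 of its members. With library sizes alone as scaling, the neutrophil and stellate cell calls ended (camera adjusted p = 0.064 and 0.08).

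Among the largest changes in fasted livers, Spon2, a secreted matrix protein (ENSMUSG00000037379, chromosome 5, 33198184 to 33218455 in GRCm38), rose from 1.87 ± 0.386 to 6.36 ± 2.08 CPM (log2 1.77 ± 0.19, edgeR adjusted p = 6.5e-06), and Cfd fell from 13.8 ± 14.3 to 0.592 ± 0.554 CPM (log2 -4.56 ± 1.03, edgeR adjusted p = 0.011). The fall of Cfd rested on ad libitum fasted livers 3, 4 and 6 (25.1, 31.2 and 23.9 CPM), since livers 1, 2 and 5 (1.1, 1.3 and 0.5 CPM) lay at the level of the TRF livers (0 to 1.6 CPM), and it went to log2 -5.23 without TRF fasted liver 2. Some large changes rested on TRF fasted liver 1. Without it Cyp2a4 went from log2 5.77 to -2.15 (edgeR adjusted p = 0.019), Ly6d, a surface antigen, from 2.77 to 1.18 (edgeR adjusted p = 0.16), and Fgf21, a fasting hormone, from 2.12 to 0.82 (edgeR adjusted p = 0.29). Pcsk9, which directs the LDL receptor to degradation, fell (log2 -1.75 ± 0.45, edgeR adjusted p = 0.024), a call that ended in 5 of 12 fits with 1 liver left out (edgeR adjusted p up to 0.059). Of the genes read in every comparison, those not passing in fasted livers had log2 values of -0.27 for Ldlr, 0.31 for Cyp7a1, -0.55 for Srebf1, -0.41 for Scd1, 0.40 for Pck1, 0.42 for Cpt1a, 0.32 for Hmgcs2, 0.58 for Igfbp1 and -0.23 for Per2 (edgeR adjusted p from 0.12 to 0.65). Of these, Srebf1 passed without TRF fasted liver 2. For TRF minus ad libitum, fasted, 955 genes passed, 548 higher and 407 lower, and 390 changed by at least 1.5-fold. With library sizes alone as scaling, the split was 678 higher and 231 lower. Camera called 20 of 46 lists, 7 higher and 13 lower and fry called 6. The count of genes was 1970 by limma-voom with sample weights, 573 without ad libitum fasted liver 2 and 481 without ad libitum fasted liver 6.

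Averaging over both states, with 12 livers per regimen, asked for the mean effect of TRF, which need not be the same in both states. Gck had log2 -0.01 in fed and -1.27 in fasted livers, and Per2 had 0.94 and -0.23. In the mean 10 of 18 xenobiotic genes were lower, and 10 of 19 extracellular matrix and 7 of 17 acute phase genes were higher. Of these lists, only the xenobiotic one was called with an estimated correlation. Cyp2c29 fell (log2 -1.55 ± 0.14, edgeR adjusted p = 4.4e-07), as did Gclc, of glutathione synthesis (log2 -0.66 ± 0.09, edgeR adjusted p = 4.3e-05) and Hmgcs1, which makes the substrate of Hmgcr (log2 -0.80 ± 0.10, edgeR adjusted p = 2.5e-05). Of 18 xenobiotic genes, 10 fell and 8 did not pass (camera adjusted p = 3.3e-12, adjusted p = 0.042 with an estimated correlation). Among members adjusted over the list alone, 1 rose and 13 fell. Of 5 clock genes of the opposite phase, 3 fell and 2 did not pass (camera adjusted p = 0.00036, adjusted p = 0.022 with an estimated correlation). Using p adjusted over the list alone, 3 fell. Of 12 E-box and D-box clock genes, 7 rose, 1 fell and 4 did not pass (camera adjusted p = 4.4e-06, adjusted p = 0.17 with an estimated correlation). Once adjusted over the list alone, 7 rose and 1 fell. Of 19 extracellular matrix genes, 10 rose and 9 did not pass (camera adjusted p = 1.6e-05, adjusted p = 0.65 with an estimated correlation). With p adjusted over the list alone, 12 rose. Col4a1, a basement membrane collagen, rose (log2 0.70 ± 0.17, edgeR adjusted p = 0.0074), with 84 to 102.8 CPM in TRF fed livers 3, 5 and 6 but 46.2 to 46.7 CPM in livers 1, 2 and 4 (ad libitum fed 31.1 to 47.1 CPM). In TRF fasted liver 1 it was at 127.8 CPM, and in the other 5 at 50.3 to 79.1 CPM (ad libitum fasted 36.7 to 65.5 CPM). Of 17 acute phase genes, 7 rose and 10 did not pass (camera adjusted p = 0.0013, adjusted p = 0.66 with an estimated correlation). Counting members adjusted over the list alone, 12 rose. Lcn2, which binds iron carriers, was at 106 ± 19.4 and 146 ± 103 CPM in ad libitum fed and fasted livers and 468 ± 376 and 419 ± 332 CPM in TRF fed and fasted livers (log2 1.83 ± 0.48, edgeR adjusted p = 0.015). Lcn2 was at 47.7 CPM in TRF fed liver 2 (ad libitum fed 79.4 to 128 CPM) and at 27.4 and 97.3 CPM in TRF fasted livers 2 and 4 (ad libitum fasted 91.4 to 353.1 CPM). Saa1, an acute phase protein, was at 217.2 CPM in TRF fed liver 2 (ad libitum fed 380.9 to 588.9 CPM) and at 201.8, 161.1 and 420.5 CPM in TRF fasted livers 1, 2 and 4 (ad libitum fasted 395.1 to 4324.3 CPM). Of 8 neutrophil markers, 3 rose and 5 did not pass (camera adjusted p = 0.0014, adjusted p = 0.65 with an estimated correlation). With members adjusted over the list alone, 8 rose. DESeq2 called 7 of them and limma-voom 0. Of 7 cholangiocyte markers, 3 rose and 4 did not pass (camera adjusted p = 0.006, adjusted p = 0.65 with an estimated correlation). When adjusted over the list alone, 6 rose. Of 22 cell cycle genes, 3 rose and 19 did not pass (camera adjusted p = 0.0011, adjusted p = 0.66 with an estimated correlation). If adjusted over the list alone, 13 rose. Without TRF fasted liver 1 the mitotic cyclin Ccnb2 went from log2 0.88 to 0.57 (edgeR adjusted p = 0.049) and the helicase subunit Mcm6 from 0.54 to 0.31 (edgeR adjusted p = 0.024). The call of Ccnb2 ended without TRF fed liver 3 (edgeR adjusted p up to 0.054) and that of Mcm6 ended in 9 of 24 fits with 1 liver left out (edgeR adjusted p up to 0.072).

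In the mean of both states, further lists called were cholesterol synthesis (5 fell of 23, 5 fell adjusted over the list alone), fatty acid synthesis (5 fell of 21, 6 fell adjusted over the list alone), bile acid synthesis (1 rose and 3 fell of 14, 2 rose and 6 fell adjusted over the list alone), NRF2 targets (2 fell of 15, 2 fell adjusted over the list alone) and ER chaperones (3 fell of 18, 6 fell adjusted over the list alone), with camera adjusted p from 0.00019 to 0.015, and adjusted p from 0.65 to 0.71 with an estimated correlation. The others were interferon response (4 fell of 19, 6 fell adjusted over the list alone), oxidative phosphorylation (5 fell of 24, 6 fell adjusted over the list alone), Kupffer cells (2 fell of 12, 5 fell adjusted over the list alone), B cells and plasma cells (3 fell of 8, 5 fell adjusted over the list alone) and mitochondrially encoded genes (3 fell of 19, 6 fell adjusted over the list alone), with camera adjusted p from 0.00036 to 0.014, and adjusted p from 0.65 to 0.66 with an estimated correlation. Calls ended for bile acid synthesis without TRF fasted liver 1 (camera adjusted p up to 0.17), for interferon response without TRF fed liver 2 (camera adjusted p up to 0.058) and for Kupffer cells without ad libitum fasted liver 4 (camera adjusted p up to 0.052). Of the genes read in every comparison, Gck (log2 -0.64 ± 0.14, edgeR adjusted p = 0.0042) and Arntl (log2 -1.04 ± 0.14, edgeR adjusted p = 6.3e-05) fell and Nr1d1 rose (log2 1.27 ± 0.20, edgeR adjusted p = 0.00034). Pck1 (log2 0.75 ± 0.25, edgeR adjusted p = 0.048) and Per2 (log2 0.36 ± 0.11, edgeR adjusted p = 0.029) rose but lost their calls in 21 and 6 of 24 fits with 1 liver left out. The rest had log2 values of -0.17 for Ldlr, 0.38 for Cyp7a1, -0.18 for Hmgcr, -0.52 for Pcsk9, -0.13 for Srebf1, -0.72 for Fasn, -0.45 for Scd1, 0.18 for Cpt1a, 0.06 for Hmgcs2, 0.87 for Fgf21 and 1.10 for Igfbp1 (edgeR adjusted p from 0.091 to 0.78). Of these, Fgf21 was log2 0.23 without TRF fasted liver 1 (edgeR adjusted p = 0.66) and Igfbp1 passed without ad libitum fed liver 1 or TRF fed liver 1. For TRF minus ad libitum, mean of fed and fasted, 2098 genes passed, 1153 higher and 945 lower, and 530 changed by at least 1.5-fold. With library sizes alone the split was 1247 higher and 636 lower, and limma-voom called 3249 genes. Camera called 18 of 46 lists, 6 higher and 12 lower, and fry called 8. With an estimated correlation camera called 2, xenobiotic genes and clock genes of the opposite phase. The effects of TRF in the 2 states, which share no library, correlated at Pearson r = 0.29 and Spearman rho = 0.24 over 14967 genes, which are not independent replicates. Calls shared were 84 upwards (31.5 for independent lists of these sizes) and 86 downwards (21), with 56 in opposite directions. Hspa8, chosen here after its value was seen, was among the last, since it rose in fed livers (log2 0.58 ± 0.15, edgeR adjusted p = 0.012).

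The next comparison asked how fasted and fed livers differed under ad libitum feeding. Clock genes were among those that changed most, and 5 of 13 gluconeogenesis genes were higher in fasted livers. With an estimated correlation only the clock lists were called. Dbp (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203 in GRCm38) rose from 3.79 ± 1.63 to 59.4 ± 13.9 CPM (log2 3.97 ± 0.22, edgeR adjusted p = 6.6e-12, n = 6 per group). Arntl (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126) fell from 24.3 ± 3.11 to 2.46 ± 1.28 CPM (log2 -3.28 ± 0.20, edgeR adjusted p = 2.5e-11). Pck1 rose from 696 ± 536 to 2648 ± 754 CPM (log2 1.93 ± 0.36, edgeR adjusted p = 0.0011), and Gck fell from 302 ± 79.2 to 172 ± 55.4 CPM (log2 -0.81 ± 0.20, edgeR adjusted p = 0.0095). Cpt1a, which admits fatty acids to mitochondria, rose from 354 ± 109 to 584 ± 82.1 CPM (log2 0.72 ± 0.19, edgeR adjusted p = 0.014).

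Of 12 E-box and D-box clock genes under ad libitum feeding, 8 rose, 1 fell and 3 did not pass (camera adjusted p = 6.3e-33, adjusted p = 4.8e-05 with an estimated correlation). By p-values adjusted over the list alone, 9 rose and 1 fell. All 5 clock genes of the opposite phase fell (camera adjusted p = 2.5e-21, adjusted p = 3.5e-07 with an estimated correlation). Where p was adjusted over the list alone, 5 fell. Of 13 gluconeogenesis genes, 5 rose and 8 did not pass (camera adjusted p = 0.00015, adjusted p = 0.56 with an estimated correlation). Among members adjusted over the list alone, 6 rose. Of 18 ER chaperones, 5 fell and 13 did not pass (camera adjusted p = 6.2e-05, adjusted p = 0.79 with an estimated correlation). Using p adjusted over the list alone, 1 rose and 15 fell. Of 13 heat shock genes, 5 fell and 8 did not pass (camera adjusted p = 0.002, adjusted p = 0.79 with an estimated correlation). Once adjusted over the list alone, 6 fell. Of 14 insulin-repressed FOXO targets, 4 rose, 1 fell and 9 did not pass (camera adjusted p = 0.037, adjusted p = 0.56 with an estimated correlation). With p adjusted over the list alone, 4 rose and 1 fell. The one that fell was Pdk4, a kinase, chosen after its value was seen, and the call of the list ended in 4 of 12 fits with 1 liver left out (camera adjusted p up to 0.098). Of 14 lipid droplet genes, 1 rose, 1 fell and 12 did not pass (camera adjusted p = 0.037, adjusted p = 0.79 with an estimated correlation). Counting members adjusted over the list alone, 1 rose and 1 fell. The lipid droplet call ended in 6 of 12 fits with 1 liver left out (camera adjusted p up to 0.18). The list of cytosolic ribosomal proteins was called downwards (camera adjusted p = 4.3e-06, adjusted p = 0.94 with an estimated correlation) with 0 of 78 members past the edgeR threshold and 0 adjusted over the list alone. In this list, 16 were lower at an unadjusted p under 0.05, with 0 called by DESeq2 and 0 by limma-voom. Other called lists were interferon response (1 rose of 19, 1 rose adjusted over the list alone), pericentral hepatocytes (2 rose of 12, 2 rose adjusted over the list alone), B cells and plasma cells (1 rose of 8, 1 rose adjusted over the list alone) and oxidative phosphorylation (1 fell of 24, none passed adjusted over the list alone), with camera adjusted p from 0.011 to 0.048, and adjusted p from 0.79 to 0.94 with an estimated correlation. Of the oxidative phosphorylation genes, 7 were lower at an unadjusted p under 0.05, 2 by DESeq2 and 1 by limma-voom. The pericentral call ended in 7 of 12 fits with 1 liver left out (camera adjusted p up to 0.12), and the B cell call ended without ad libitum fed liver 1 or ad libitum fasted liver 6 (camera adjusted p up to 0.094).

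Decreases of the pancreatic proteases Ctrb1 and Ctrl rested on ad libitum fed liver 3. Without it they went from log2 -9.22 to -1.85 (edgeR adjusted p = 0.77) and from -5.09 to 0.03 (edgeR adjusted p = 0.99). Hspa5, the main ER chaperone, went from log2 -0.87 to -0.53 (edgeR adjusted p = 0.095) without ad libitum fed liver 4, and its call also ended without ad libitum fasted livers 3 or 4. Nr1d1 rose (log2 3.88 ± 0.31, edgeR adjusted p = 1.6e-08), and so did Hmgcr (log2 0.80 ± 0.22, edgeR adjusted p = 0.025), a call that ended in 5 of 12 fits with 1 liver left out (edgeR adjusted p up to 0.076). Genes read in every comparison that did not pass under ad libitum feeding had log2 values of 0.19 for Ldlr, 0.41 for Cyp7a1, 0.21 for Pcsk9, -0.02 for Srebf1, -0.29 for Fasn, -0.09 for Scd1, -0.16 for Hmgcs2, -1.17 for Fgf21, 0.30 for Igfbp1 and 0.11 for Per2 (edgeR adjusted p from 0.29 to 0.97). Of these, Igfbp1 was log2 0.90 without ad libitum fed liver 1 (edgeR adjusted p = 0.44). For fasted minus fed, ad libitum, 1345 genes passed, 656 higher and 689 lower, and 619 changed by at least 1.5-fold, while limma-voom called 2202. Camera called 12 of 46 lists, 6 in each direction and fry called 4.

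**Figure D2:**
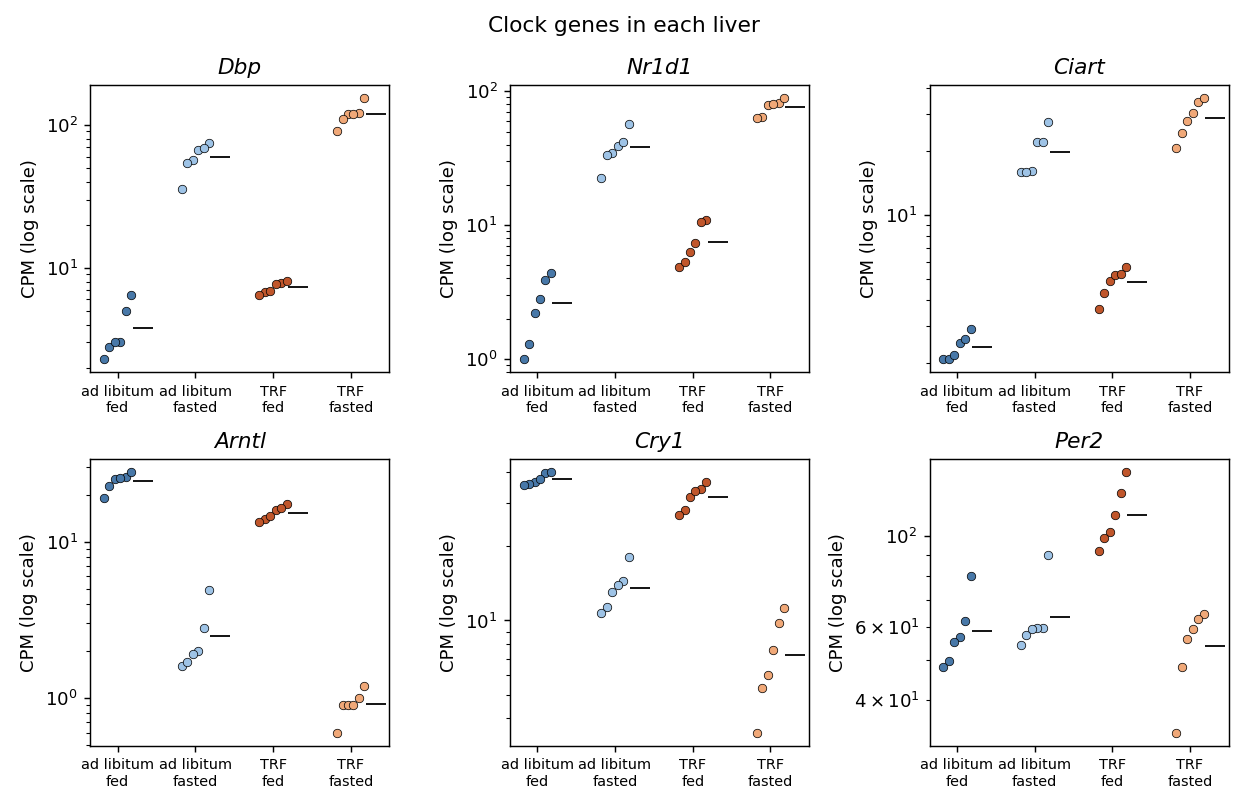
Levels of 6 clock genes in CPM on a log axis, by group. Each point is 1 liver (n = 6 per group) and the line is the group mean. Dbp lies between 2.3 and 6.5 CPM in ad libitum fed and between 35.7 and 74.5 CPM in ad libitum fasted livers, against 6.5 to 8.1 CPM and 90.4 to 154.2 CPM under TRF.

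The corresponding comparison asked how fasted and fed livers differed under TRF. All 13 heat shock genes and 9 of 21 fatty acid synthesis genes were lower in fasted livers, and 7 of 13 gluconeogenesis genes were higher. With an estimated correlation only heat shock and the clock lists were called. Hsp90aa1, the inducible HSP90, fell from 565 ± 78.7 to 100.3 ± 22.2 CPM (log2 -2.49 ± 0.20, edgeR adjusted p = 3.1e-09, n = 6 per group). Fasn fell from 1032 ± 435 to 169 ± 83.2 CPM (log2 -2.61 ± 0.43, edgeR adjusted p = 7.2e-05), and Insig1, a brake on cholesterol synthesis, fell from 336 ± 99.2 to 78.7 ± 15.6 CPM (log2 -2.09 ± 0.27, edgeR adjusted p = 3.2e-06). Sds, which makes pyruvate from serine, rose from 85.9 ± 19 to 281 ± 102 CPM (log2 1.71 ± 0.20, edgeR adjusted p = 6.9e-07). Trib3 rose from 1.42 ± 0.262 to 14 ± 8.68 CPM (log2 3.30 ± 0.31, edgeR adjusted p = 2.4e-08).

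All 13 heat shock genes under TRF fell (camera adjusted p = 5.7e-25, adjusted p = 0.011 with an estimated correlation). With members adjusted over the list alone, 13 fell. Of 18 ER chaperones, 16 fell and 2 did not pass (camera adjusted p = 4.6e-10, adjusted p = 0.58 with an estimated correlation). When adjusted over the list alone, 17 fell. Of 12 E-box and D-box clock genes, 8 rose, 2 fell and 2 did not pass (camera adjusted p = 2.1e-10, adjusted p = 0.026 with an estimated correlation). If adjusted over the list alone, 9 rose and 2 fell. Those that fell were Rorc, chosen after its value was seen, and Per2 (from 113 ± 19.6 to 54.1 ± 11.8 CPM, log2 -1.06 ± 0.16, edgeR adjusted p = 1.2e-05). Of 5 clock genes of the opposite phase, 4 fell and 1 did not pass (camera adjusted p = 1.9e-11, adjusted p = 3.3e-05 with an estimated correlation). By p-values adjusted over the list alone, 4 fell. Dbp rose from 7.31 ± 0.652 to 119 ± 20.7 CPM (log2 4.02 ± 0.21, edgeR adjusted p = 5.5e-12), and Arntl fell from 15.3 ± 1.54 to 0.945 ± 0.195 CPM (log2 -4.02 ± 0.22, edgeR adjusted p = 5.5e-12). Of 23 cholesterol synthesis genes, 1 rose, 10 fell and 12 did not pass (camera adjusted p = 0.00016, adjusted p = 0.71 with an estimated correlation). Where p was adjusted over the list alone, 1 rose and 10 fell. Of 21 fatty acid synthesis genes, 9 fell and 12 did not pass (camera adjusted p = 0.0014, adjusted p = 0.77 with an estimated correlation). Among members adjusted over the list alone, 9 fell. Of 15 glycolysis genes, 1 rose, 8 fell and 6 did not pass (camera adjusted p = 0.0036, adjusted p = 0.61 with an estimated correlation). Using p adjusted over the list alone, 1 rose and 10 fell. The members that rose were Mvk, mevalonate kinase, and Slc2a2, a glucose transporter, both chosen after their values were seen, and Gck fell from 299 ± 50 to 71.1 ± 17.4 CPM (log2 -2.07 ± 0.21, edgeR adjusted p = 6e-08). Of 13 gluconeogenesis genes, 7 rose and 6 did not pass (camera adjusted p = 0.016, adjusted p = 0.71 with an estimated correlation). Once adjusted over the list alone, 7 rose and 1 fell. The call of gluconeogenesis ended without TRF fed liver 4 (camera adjusted p up to 0.073).

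Of 20 autophagy and lysosome genes, 6 rose and 14 did not pass (camera adjusted p = 0.016, adjusted p = 0.61 with an estimated correlation). With p adjusted over the list alone, 6 rose. Of 14 insulin-repressed FOXO targets, 7 rose and 7 did not pass (camera adjusted p = 0.026, adjusted p = 0.45 with an estimated correlation). Counting members adjusted over the list alone, 7 rose and 2 fell. The FOXO call ended without TRF fed liver 4 (camera adjusted p up to 0.067). Of 8 B cell and plasma cell markers, 6 rose and 2 did not pass (camera adjusted p = 0.0012, adjusted p = 0.61 with an estimated correlation). With members adjusted over the list alone, 7 rose. Of 78 cytosolic ribosomal protein genes, 17 fell and 61 did not pass (camera adjusted p = 1.5e-05, adjusted p = 0.97 with an estimated correlation). When adjusted over the list alone, 14 fell. Of 24 oxidative phosphorylation genes, 6 fell and 18 did not pass (camera adjusted p = 0.026, adjusted p = 0.97 with an estimated correlation). If adjusted over the list alone, 5 fell. This last call ended in 4 of 12 fits with 1 liver left out (camera adjusted p up to 0.12), and with library sizes alone as scaling (camera adjusted p = 0.11). Without TRF fasted liver 1 Cyp2a4 went from log2 7.44 to -0.48 (edgeR adjusted p = 0.61), and without TRF fed liver 3 Slc4a1 went from log2 -2.83 to -0.77 (edgeR adjusted p = 0.41), with a call that also ended without TRF fasted livers 2 or 4. Of the genes read in every comparison, Pcsk9 (log2 -2.26 ± 0.46, edgeR adjusted p = 0.00075), Srebf1, a regulator of lipid synthesis (log2 -0.86 ± 0.21, edgeR adjusted p = 0.0029), and Hmgcr (log2 -0.83 ± 0.22, edgeR adjusted p = 0.0066) fell. Cpt1a (log2 1.19 ± 0.19, edgeR adjusted p = 2.8e-05), Pck1 (log2 1.23 ± 0.36, edgeR adjusted p = 0.011) and Nr1d1 (log2 3.34 ± 0.29, edgeR adjusted p = 2.3e-08) rose. Those not passing under TRF had log2 values of 0 for Ldlr, 0.27 for Cyp7a1, -0.01 for Scd1, 0.36 for Hmgcs2, 1.32 for Fgf21 and -0.74 for Igfbp1 (edgeR adjusted p from 0.1 to 0.99). Of these, Fgf21 was log2 0.03 without TRF fasted liver 1 (edgeR adjusted p = 0.97), Cyp7a1 passed without TRF fed liver 2, Hmgcs2 passed without TRF fed liver 2 or TRF fasted liver 1 and Fgf21 passed without TRF fasted liver 4.

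For fasted minus fed, TRF, 4488 genes passed, 2224 higher and 2264 lower, and 2022 changed by at least 1.5-fold. With library sizes alone as scaling, the split was 2831 higher and 1447 lower. Camera called 13 of 46 lists, 5 higher and 8 lower, and fry called 16. Changes between fasted and fed livers under the 2 regimens, which share no library, correlated at Pearson r = 0.53 and Spearman rho = 0.5 over 14967 genes, which are not independent replicates. Calls shared were 475 upwards (97.5 for independent lists of these sizes) and 427 downwards (104), with 25 in opposite directions.

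**Figure D3:**
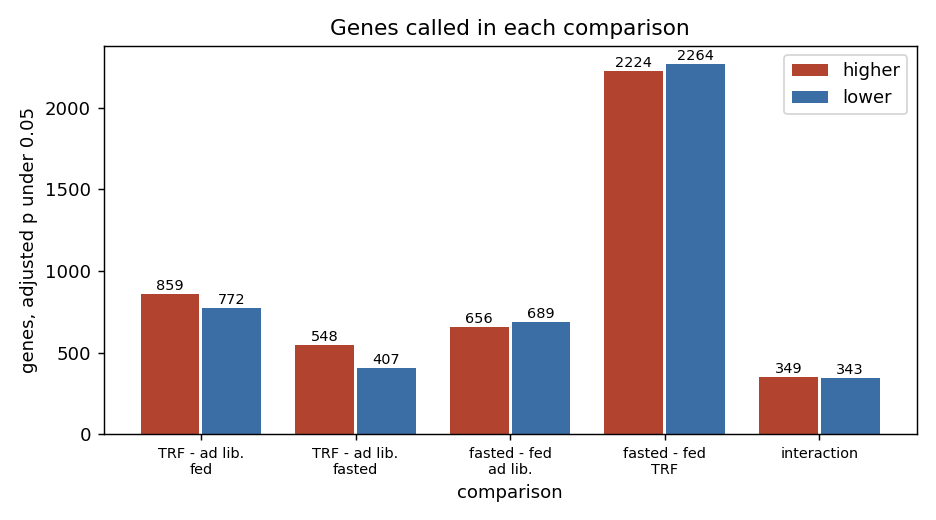
Number of genes past the threshold in 5 comparisons, with bars for genes higher and lower in the first-named group. The bars for fasted against fed livers under TRF reach 2224 higher and 2264 lower, against 656 and 689 under ad libitum feeding.

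The interaction asked whether the change between states differed between regimens, where a positive value means a higher fasted to fed ratio under TRF. The ratio was lower under TRF for 12 of 13 heat shock genes, 7 of 23 cholesterol synthesis genes and 7 of 21 fatty acid synthesis genes. Only the heat shock list was called with an estimated correlation, and under ad libitum feeding neither synthesis list was called. Hspa8 was at 1766 ± 323 and 1238 ± 249.6 CPM in ad libitum fed and fasted livers and 2633 ± 352 and 773 ± 116 CPM in TRF fed and fasted livers (interaction log2 -1.25 ± 0.21, edgeR adjusted p = 0.00089, n = 6 per group). Insig1 (ENSMUSG00000045294, chromosome 5, 28071363 to 28078662 in GRCm38) was at 205 ± 70.1 and 233 ± 86.9 CPM in ad libitum fed and fasted livers and 336 ± 99.2 and 78.7 ± 15.6 CPM in TRF fed and fasted livers (interaction log2 -2.28 ± 0.37, edgeR adjusted p = 0.00096). Gck was at 302 ± 79.2 and 172 ± 55.4 CPM in ad libitum fed and fasted livers and 299 ± 50 and 71.1 ± 17.4 CPM in TRF fed and fasted livers (interaction log2 -1.26 ± 0.28, edgeR adjusted p = 0.0097). Trib3 was at 1.94 ± 0.344 and 2.81 ± 1.01 CPM in ad libitum fed and fasted livers and 1.42 ± 0.262 and 14 ± 8.68 CPM in TRF fed and fasted livers (interaction log2 2.77 ± 0.42, edgeR adjusted p = 0.00047).

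Of 13 heat shock genes in the interaction, 12 went down and 1 did not pass (camera adjusted p = 4.6e-25, adjusted p = 0.023 with an estimated correlation). By p-values adjusted over the list alone, 13 went down. Of 23 cholesterol synthesis genes, 7 went down and 16 did not pass (camera adjusted p = 3.2e-10, adjusted p = 0.82 with an estimated correlation). Where p was adjusted over the list alone, 10 went down. Hmgcr was at 52.5 ± 13.7 and 91.1 ± 30.1 CPM in ad libitum fed and fasted livers and 81.2 ± 24.6 and 45.7 ± 7.73 CPM in TRF fed and fasted livers (interaction log2 -1.62 ± 0.32, edgeR adjusted p = 0.0037). Of 21 fatty acid synthesis genes, 7 went down and 14 did not pass (camera adjusted p = 2.7e-06, adjusted p = 0.96 with an estimated correlation). Among members adjusted over the list alone, 1 went up and 8 went down. Of 15 glycolysis genes, 1 went down and 14 did not pass (camera adjusted p = 0.0063, adjusted p = 0.96 with an estimated correlation). Using p adjusted over the list alone, 1 went down. Of 22 cell cycle genes, 1 went down and 21 did not pass (camera adjusted p = 0.039, adjusted p = 0.96 with an estimated correlation). Once adjusted over the list alone, 1 went down. The cell cycle call ended in 14 of 24 fits with 1 liver left out (camera adjusted p up to 0.16). The list of fatty acid oxidation and ketogenesis was called upwards (camera adjusted p = 0.0079, adjusted p = 0.96 with an estimated correlation) with 0 of 34 members past the edgeR threshold and 0 adjusted over the list alone. In the whole list, 6 were higher at an unadjusted p under 0.05, with 0 called by DESeq2 and 3 by limma-voom. The oxidation call ended without ad libitum fasted liver 5 or TRF fasted liver 3 (camera adjusted p up to 0.067). The ER chaperone list was called downwards (camera adjusted p = 0.00012, adjusted p = 0.96 with an estimated correlation) with 0 of 18 members past the edgeR threshold and 0 adjusted over the list alone. Of all its members, 6 were lower at an unadjusted p under 0.05, with 0 called by DESeq2 and 2 by limma-voom.

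Among the largest interactions, Spon2 was at 6.39 ± 1.3 and 1.87 ± 0.386 CPM in ad libitum fed and fasted livers and 2.78 ± 0.494 and 6.36 ± 2.08 CPM in TRF fed and fasted livers (interaction log2 2.97 ± 0.27, edgeR adjusted p = 4.1e-07). Per2 was at 58.6 ± 11.7 and 63.4 ± 13.1 CPM in ad libitum fed and fasted livers and 113 ± 19.6 and 54.1 ± 11.8 CPM in TRF fed and fasted livers (interaction log2 -1.18 ± 0.22, edgeR adjusted p = 0.0023). The interaction of Pcsk9 (log2 -2.47 ± 0.63, edgeR adjusted p = 0.027) lost its call without ad libitum fasted liver 5 or TRF fed liver 5 (edgeR adjusted p up to 0.056). Genes read in every comparison whose interaction did not pass had log2 values of -0.19 for Ldlr, -0.14 for Cyp7a1, -0.84 for Srebf1, 0.08 for Scd1, -0.70 for Pck1, 0.47 for Cpt1a, 0.52 for Hmgcs2, 2.49 for Fgf21, -1.04 for Igfbp1, -0.73 for Arntl, 0.05 for Dbp and -0.54 for Nr1d1 (edgeR adjusted p from 0.11 to 0.95). Of these, Fgf21 was log2 1.19 without TRF fasted liver 1 (edgeR adjusted p = 0.28), Igfbp1 was log2 -1.63 without ad libitum fed liver 1 (edgeR adjusted p = 0.35), Srebf1 passed without TRF fasted liver 2 and Hmgcs2 passed without TRF fasted liver 1. For the difference of the fasted minus fed change, TRF minus ad libitum, 692 genes passed, 349 upwards and 343 downwards, 493 of them by at least 1.5-fold. With library sizes alone as scaling, the split was 386 upwards and 191 downwards. Camera called 7 of 46 lists, 1 upwards and 6 downwards, and fry called heat shock alone. The count of genes was 1267 by limma-voom, 450 with no filter on low counts, 454 without ad libitum fasted liver 5 and 424 without the 3 livers with pancreatic transcripts.

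**Figure D4:**
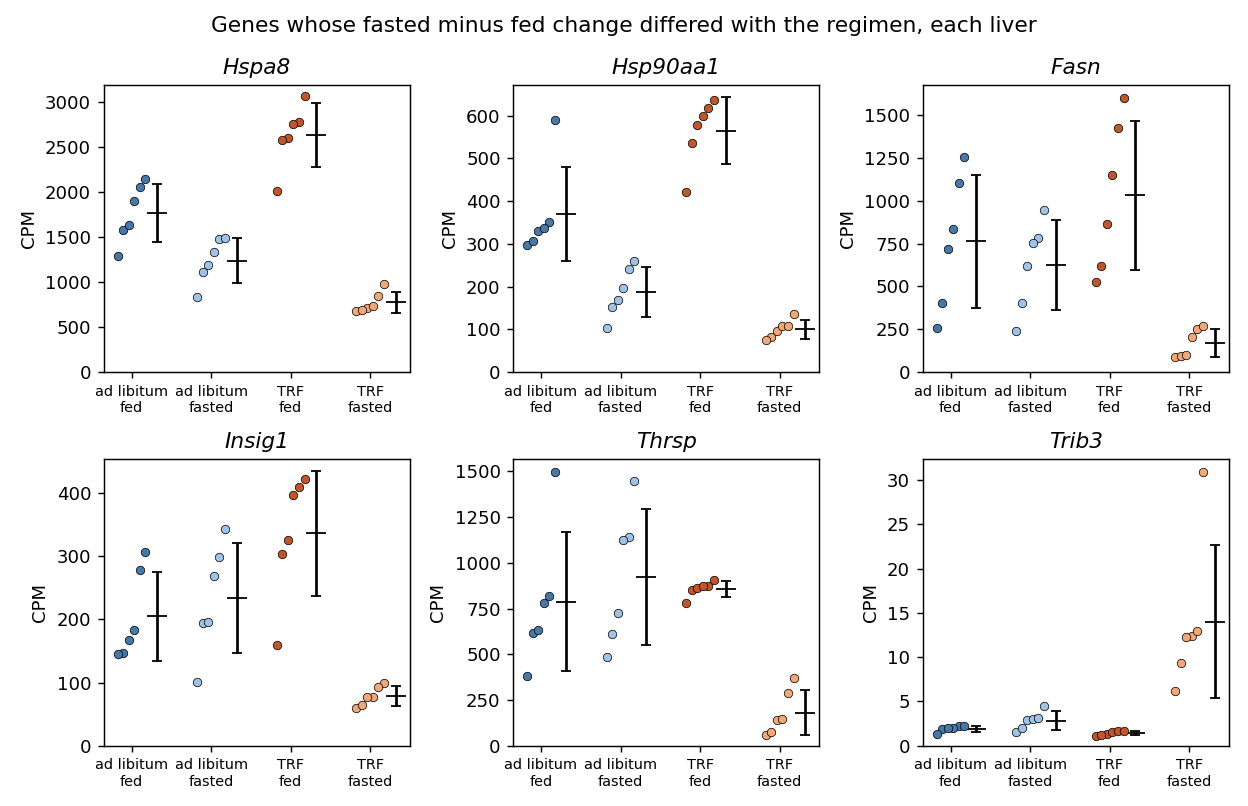
Levels in CPM of Hspa8, Hsp90aa1, Fasn, Insig1, Thrsp and Trib3 by group. Each point is 1 liver (n = 6 per group) and the bar with whiskers is the mean ± SD. Hspa8 lies between 2007.8 and 3069.3 CPM in TRF fed and between 680.4 and 976 CPM in TRF fasted livers, against 1286.3 to 2141.7 CPM and 828.4 to 1485.9 CPM under ad libitum feeding.

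**Figure D5:**
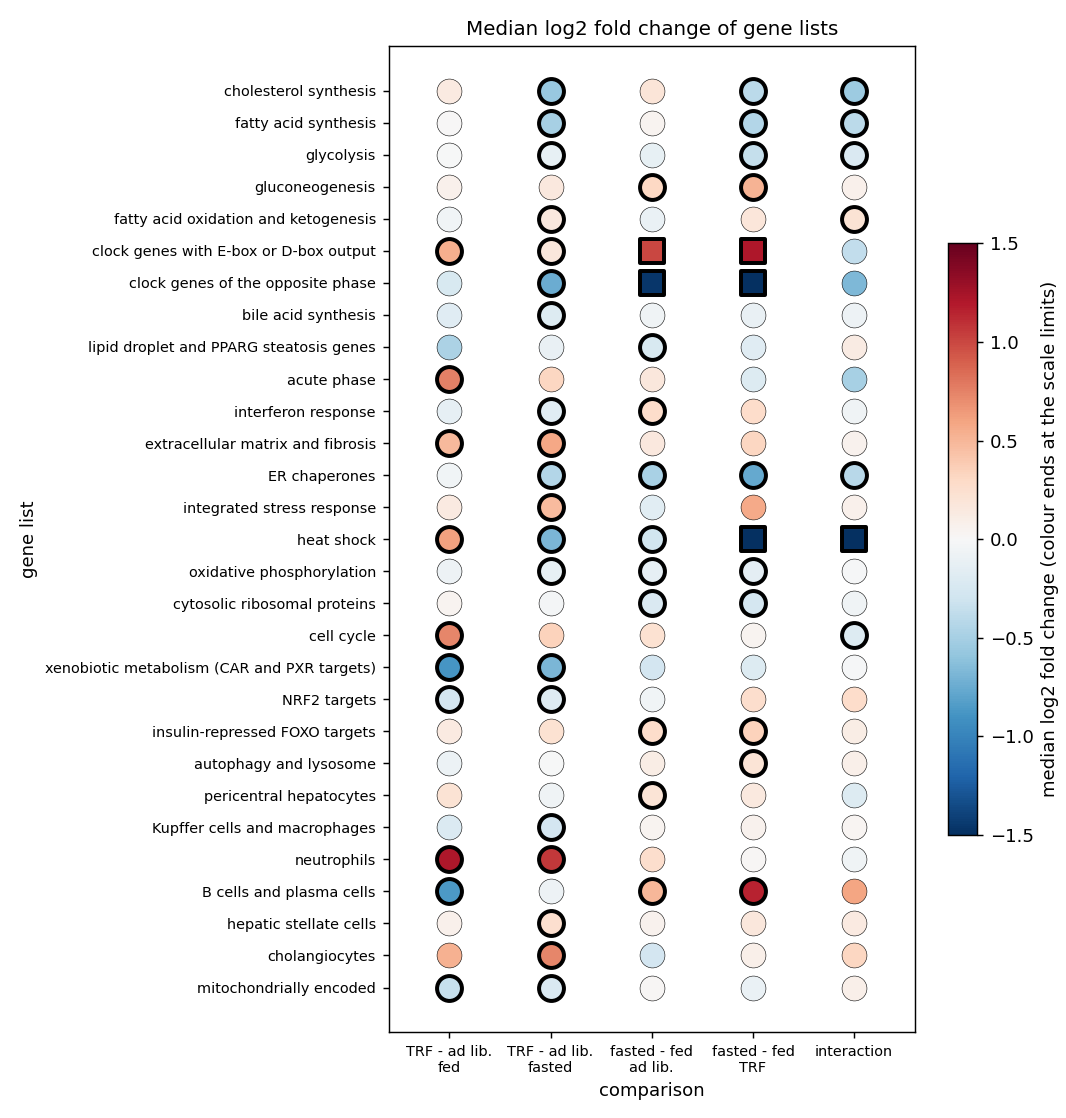
Median log2 fold change of 29 gene lists in 5 comparisons, shown by colour with the scale limited at 1.5 in either direction. A thick outline marks a camera call and a square a call that holds with an estimated correlation. The heat shock list has medians of 0.61 for TRF in fed livers and -0.69 for TRF in fasted livers. Its medians are -0.29 and -1.76 for fasted minus fed livers under ad libitum feeding and TRF, and -1.51 for the interaction.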

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

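Of the tests in this part, the 3 on TRF fasted liver 1 were chosen only after the result was seen; the others were set before their own results were. A liver was singled out where its gap to the nearest of the other 5 livers of its group, as a share of the group's range, passed the 5% limit of Dixon's test. Genes and lists were tested on log2 CPM, while gene values are printed as CPM. Chance passes that limit in about 1 in 20 groups. Of 552 sets of 6 values of named genes 43 did so, 12 of them because of TRF fasted liver 1, and of 184 sets of list means 18 did, 11 of them because of the same liver.

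TRF fasted liver 1 gave, with the range of the other 5 TRF fasted livers in parentheses, Aldh1a1 500 CPM (742 to 827), Cdkn1a 25 CPM (2.88 to 5.44), Cyp2a4 193 CPM (0 to 0.235), Dnaja1 98.6 CPM (154 to 183), Elovl3 0.242 CPM (51.2 to 57.9), Hmgcs2 1240 CPM (2380 to 3310), Igfbp1 98.1 CPM (21.4 to 37.4), Mcm6 26.8 CPM (6.92 to 9.64), Nat8f5 0.918 CPM (5.42 to 7.57), Slc1a2 157 CPM (266 to 335), Slc30a10 2.22 CPM (7.54 to 10.9) and Tubb2a 68.8 CPM (9.64 to 14.1). Its mean log2 CPM values were clock genes with E-box or D-box output 5.45 (5.85 to 6.06), bile acid synthesis 7.04 (8.12 to 8.23), bile acid transport 5.95 (6.41 to 6.6), integrated stress response 3.72 (2.03 to 2.45), cell cycle 2.88 (0.86 to 1.31), NRF2 targets 6.37 (4.48 to 4.69), male-biased liver genes 3.28 (8.17 to 8.53), female-biased liver genes 3.11 (-1.48 to -0.53), pericentral hepatocytes 6.42 (7.12 to 7.23), lipid-associated and recruited macrophages 6.84 (4.59 to 5.28) and cholangiocytes 3.23 (1.16 to 1.7). Its TMM factor was 1.26 (0.967 to 1.02), and its 100 most abundant genes held 41.5% of counts (45.2 to 47.3%).

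The first pattern weighed was this liver, outside the range of the other 23 in the means of male-biased (7.11 to 8.64), female-biased (-1.77 to 1.07), cell cycle (0.78 to 2.1) and recruited macrophage genes (4.37 to 5.67). A female animal was excluded by Xist at 0.061 CPM with Y-linked genes at the level of the other livers (Ddx3y 64.9 CPM), and low depth by its 32.9 M counts. A library of another group was excluded: on a scale from 0 at that group to 1 at the other TRF fasted livers, its median over 967, 4398 and 4601 genes called between them was 0.71 from ad libitum fasted, 0.8 from ad libitum fed and 0.77 from TRF fed livers, whose own livers reached at most 0.36, 0.25 and 0.33. Gpnmb, a marker of lipid-laden macrophages, stood at 536 CPM against at most 250 CPM in the other 23 livers, Mki67, a marker of dividing cells, at 22.7 against at most 20.1 CPM, and H19, a fetal liver transcript, at 12.6 against at most 0.873 CPM. A lesion or an illness of this animal stays open, and neither was tested.

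Among the other livers, each value is followed by the range of the other 5 livers of its group, gene values are in CPM and list values are mean log2 CPM. Ad libitum fed liver 1 gave Angptl8 5.69 CPM (36.6 to 89.3), Clec4f 106 CPM (158 to 199), Dtx4 14.9 CPM (25 to 27.1), Gpcpd1 86.1 CPM (25.2 to 38.2), Pax5 0.269 CPM (0.64 to 0.962), Pck1 1780 CPM (380 to 536), Serpinb1a 2.75 CPM (6.65 to 8.44), Sox9 2.9 CPM (3.82 to 4.47) and Tubb2a 68.3 CPM (136 to 183) and a mean of cholangiocytes 1.13 (1.35 to 1.48). Ad libitum fed liver 3 gave Ctrb1 148 CPM (0 to 0.587), Ctrl 53.8 CPM (0.18 to 0.347) and Nat8f5 27.1 CPM (18.8 to 21.1) and a mean of pancreatic acinar cells 6.46 (-3.01 to -1.96). Ad libitum fed liver 4 gave Acss3 8.83 CPM (17.3 to 25.7), Hsp90aa1 590 CPM (298 to 352), Rpl13a 10.2 CPM (5.43 to 6.52) and Saa1 589 CPM (381 to 429) and a mean of mitochondrially encoded 5.7 (5.09 to 5.3). Ad libitum fed liver 6 gave Trib3 1.28 CPM (1.92 to 2.22). Ad libitum fasted liver 1 gave Lcn2 353 CPM (91.4 to 141). Ad libitum fasted liver 2 gave Cxcl1 20 CPM (7.2 to 10.4). Ad libitum fasted liver 3 gave Scd1 29000 CPM (11700 to 16100). Ad libitum fasted liver 4 gave a mean of amino acid catabolism and urea cycle 9.08 (9.25 to 9.32). Ad libitum fasted liver 5 gave Ifi44 7.51 CPM (10.4 to 12.6), Per2 89.8 CPM (54.2 to 59.9) and Usp18 9.42 CPM (12.9 to 14.4). Ad libitum fasted liver 6 gave Akr1c6 1710 CPM (1210 to 1360) and a mean of erythrocytes 5.9 (3.4 to 4.28). TRF fed liver 2 gave Acss3 15.6 CPM (3.43 to 5.5), Angptl8 19.4 CPM (84.6 to 119), Insig1 159 CPM (303 to 422), Saa1 217 CPM (1900 to 5590) and Saa2 80.9 CPM (1040 to 4400) and a mean of fatty acid oxidation and ketogenesis 7.23 (6.47 to 6.74). TRF fed liver 4 gave Srebf1 468 CPM (552 to 596) and a mean of fatty acid synthesis 7.51 (7.86 to 8.06). TRF fasted liver 3 gave Acat2 17.9 CPM (23.3 to 26.8). Total counts stood out in ad libitum fasted liver 6 at 38.4 M (27.1 to 31.3) and in TRF fed liver 4 at 23.6 M (29.2 to 32.2), and the share of counts in the 100 most abundant genes in ad libitum fed liver 4 at 48.5% (45.4 to 46.5%) and ad libitum fasted liver 2 at 47.3% (44.2 to 45%). Chance alone marks about 1 in 20 such groups.

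The fasted minus fed change, in which food and time value cannot be separated, differed between the regimens for 39 named genes by the interaction test of edgeR. Some of these were named for a large interaction, and 692 of all 14967 genes (4.62%) passed. Log2 interactions were positive for Atf5 1.71, Bhlhe41 1.04, Camk1d 1.85, Cd79b 1.22, Dtx4 1.26, Flvcr2 2, Gabarapl1 0.81, Gpcpd1 1.21, Serpinb1a 1.88, Spon2 2.97, Trib3 2.77, Trpm4 1.25, Tymp 2.54 and Wipi1 0.7. They were negative for Acat2 -0.63, Acly -1.36, Bag3 -1.53, Dnaja1 -1.16, Elovl6 -2.25, Fasn -2.32, Fdps -2.23, Gck -1.26, Hmgcr -1.62, Hsp90aa1 -1.51, Hspa1b -3.56, Hspa4l -0.92, Hspa8 -1.25, Hspb1 -1.65, Hsph1 -1.89, Insig1 -2.28, Mid1ip1 -1.37, Nat8f5 -2.42, Pcsk9 -2.47, Per2 -1.18, Pnpla3 -3.78, Ppp1r3b -1.67, Rrm2 -1.53, Steap4 -1.26 and Thrsp -2.48. Median interactions of the 7 lists called by camera were cholesterol synthesis -0.54, fatty acid synthesis -0.4, glycolysis -0.23, fatty acid oxidation and ketogenesis 0.22, ER chaperones -0.42, heat shock -1.51 and cell cycle -0.21.

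The second pattern weighed was the heat shock list, higher under TRF in fed livers and lower in fasted livers. Scaling between libraries was excluded, since the median interaction of the list was -1.44 with library sizes alone against -1.51 with TMM, and it lay between -1.64 and -1.36 in fits with 1 liver left out. A body temperature signal may be a candidate explanation: Cirbp, a cold-inducible gene outside the list, had the opposite interaction (1.08 ± 0.22 SE, edgeR adjusted p = 0.0049), but Rbm3, the other gene read for this, had 0.07, so the test decided nothing. Handling of 1 group as a batch can bear on only 1 of these changes, which share no library, and for the change in 1 state it cannot be told apart from the groups, since 0 of 24 libraries carry a batch, date or run. Feeding at different hours under the 2 regimens, which the design names, stays open.

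The third pattern weighed was that fasted and fed livers differed in 4488 genes under TRF and in 1345 under ad libitum feeding. A larger spread between ad libitum livers was excluded as the whole account, since the variance of log2 fold changes beyond their squared standard errors was 0.199 under TRF and 0.111 under ad libitum feeding over 9984 genes, a ratio of 1.79 that lay between 1.51 (without ad libitum fed liver 1) and 2.03 in fits with 1 liver left out. TRF fasted liver 1 was excluded, since 4617 genes passed under TRF without it and 1729 under ad libitum feeding. Sampling time, shared by both regimens, stays open. The 692 interaction genes, more than in 99 of 100 splits, cannot exclude it, since clock genes differed by regimen within a state. A larger contrast in recent food intake between the TRF groups is a candidate explanation, which the sources used here do not allow to be tested.

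Chance was excluded as the source of the counts of called genes in all 6 comparisons: in each, only the real one of 100 splits of the libraries (1 of 100) reached the real count. The highest other split called 306 genes against 1631 for TRF in fed livers and 58 against 955 for TRF in fasted livers. For fasted minus fed livers it called 0 against 1345 under ad libitum feeding and 1269 against 4488 under TRF. It called 154 against 692 for the interaction and 1 against 2098 for TRF in the mean of both states.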

How the results depend on the processing

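Fits without the 3 livers with pancreatic transcripts and list tests and correlations without TRF fasted liver 1 were chosen only after the data were seen. With 1 liver left out, the number of genes past the threshold lay between 926 and 1985 for TRF minus ad libitum, fed (1631 with all), 481 and 1100 for TRF minus ad libitum, fasted (955), 945 and 1557 for fasted minus fed, ad libitum (1345), 3931 and 4617 for fasted minus fed, TRF (4488), 454 and 879 for the difference of the fasted minus fed change, TRF minus ad libitum (692), and 1516 and 2491 for TRF minus ad libitum, mean of fed and fasted (2098). The lowest values came without TRF fed liver 5, ad libitum fasted liver 6, ad libitum fed liver 4, TRF fed liver 5, ad libitum fasted liver 5 and ad libitum fasted liver 6. Without a filter the count was 1077 for TRF in fed livers and 450 for the interaction, where more genes were tested. By limma-voom it was 1970 for TRF in fasted livers, 2202 for fasted minus fed, ad libitum, 1267 for the interaction and 3249 for the mean of both states. Limma-voom gave TRF fasted liver 1 a weight of 0.196, and the cause of the higher counts was not tested. Without the 3 livers with pancreatic transcripts it was 887 for TRF in fed livers and 424 for the interaction, with fewer samples. All other counts stayed within 1.5 times the reported ones.

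Of the gene lists, 80 calls were made in the 6 comparisons, 8 with an estimated correlation, which widens the test, 41 by fry, which asks another question, 84 with library sizes alone and 79 without TRF fasted liver 1. The correlations of fold changes across genes kept their sign and size with library sizes alone, with genes of at least 5 CPM and without TRF fasted liver 1. Of 275 results for named genes, 164 of 215 calls held in all fits with 1 liver left out. Under the other alternatives 2480 values kept direction and side of the threshold, 132 lost the threshold, 11 gained it and 18 changed sign. The sign changes were, by limma-voom, Cyp2a4 at -1.99 for TRF in fasted livers and -0.52 for fasting under TRF, Fgf21 at -0.08 for fasting under TRF and Cyp7a1 at 0.34 for the interaction; for fasting under ad libitum feeding, Hmgcs2 at 0.01 with the composition covariate; and for fasting under TRF, Ldlr, reported at 0, at 0 with RLE factors and DESeq2, 0.08 with library sizes alone, 0.01 without a filter, 0.02 at 5 CPM, 0.07 with the composition covariate and 0.03 by limma-voom, and Scd1 at 0.09 with library sizes alone, 0.01 without a filter and 0.01 at 5 CPM. The cause was not tested.

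Replicate numbers do not pair the livers: the correlation of deviations from the group means had a median of 0.025 over 36 same-number pairs (-0.22 to 0.32, 13 above 0.1), and 7 libraries correlated best with their own number. With the number as a replicate block, 1772 genes passed for TRF minus ad libitum, fed, 1011 for TRF minus ad libitum, fasted, 1430 for fasted minus fed, ad libitum, 4570 for fasted minus fed, TRF, 684 for the difference of the fasted minus fed change, TRF minus ad libitum, and 2274 for TRF minus ad libitum, mean of fed and fasted. Srebf1 turned to 0.01 for fasted minus fed, ad libitum, and for fasted minus fed, TRF, Ldlr turned to 0 and Scd1 to 0.02. At 23.6 to 38.7 M counts, scarce markers of immune cells such as Cd79b, at 0.497 CPM in TRF fed livers, rest on few counts.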

Other observations

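The genes in this paragraph were chosen only after their values were seen. Transporters that move cholesterol into bile differed between fasted and fed livers, where food and time value cannot be separated. Abcg8 was at 125 ± 28.1 in ad libitum fed, 272 ± 32.1 in ad libitum fasted, 70.1 ± 19.1 in TRF fed and 228 ± 30.5 CPM in TRF fasted livers (n = 6 each). It was higher in fasted livers under ad libitum feeding (log2 1.12 ± 0.16, edgeR adjusted p = 2.5e-05) and TRF (log2 1.70 ± 0.16, edgeR adjusted p = 2.3e-08), as was its partner Abcg5 (log2 1.04 ± 0.14, edgeR adjusted p = 2.7e-06 under TRF). Npas2, a partner of Arntl in the clock, was at 3.57 ± 2.51 CPM in ad libitum fed, 0.0909 ± 0.0819 CPM in ad libitum fasted, 0.0767 ± 0.0752 CPM in TRF fed and 0.158 ± 0.0851 CPM in TRF fasted livers, with an interaction of 6.37 ± 1.15 SE (edgeR adjusted p = 0.0022).

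Relations between gene groups (3) were tested on deviations from the group means over 24 livers, with 2-sided p-values from 100000 permutations adjusted over the 3. Livers with more acute phase transcripts held more metallothionein transcripts (Pearson r = 0.74, permutation p = 0.0017, adjusted 0.0049; Spearman rho = 0.66, permutation p = 0.0049, adjusted 0.015); r was 0.7 without the 2 most extreme livers, 0.82 without TRF fasted liver 1, and 0.56, 0.1, 0.98 and 0.77 within ad libitum fed, ad libitum fasted, TRF fed and TRF fasted livers. Livers with more acute phase transcripts did not hold fewer male-biased transcripts (r = 0.34, permutation p = 0.38, adjusted 0.38; rho = 0.36, permutation p = 0.056, adjusted 0.056; r = 0.33 without the 2 most extreme livers). Livers with more lipid droplet transcripts held more female-biased transcripts (r = 0.62, rho = 0.64). This relation was chosen after its values were seen, unlike the others, so no p is given. Its r was 0.59 without the 2 most extreme livers and 0.81 without TRF fasted liver 1. Within the groups in the order above it was 0.33, 0.97, 0.43 and 0.56. The 0.97 came with the split of ad libitum fasted livers 1, 2 and 5 from 3, 4 and 6. What accounts for these relations was not tested.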
